A study of Homo sapiens with 12 samples.

How the data were processed

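The 12 libraries are poly(A) RNA-seq libraries of HEK293T cells, a transformed human embryonic kidney line. Per the labels' protocols, 200 ng of an effector vector and 200 ng of a guide RNA vector were transfected together, and RNA was collected 48 hours later with DNase treatment on the column. Libraries were made from 500 ng of total RNA with a directional kit and sequenced as 150 nt read pairs, per the labels' protocols. The effectors were dCasRx, the catalytically dead form of the RNA-targeting nuclease CasRx; dCasRx-RBM25, which joins it to the splicing factor RBM25; and RBFOX1N-dCasRx-C, which joins it to parts of the splicing factor RBFOX1. The guide RNA was a nontargeting one (NT), one for activation of exon 10 of MAPT, or one for repression of exon 13 of CD46. The 6 groups are named by effector and guide as dCasRx_NT, RBM25_NT, RBM25_MAPT, RBM25_CD46, RBFOX1N_NT and RBFOX1N_MAPT. Each group has 2 replicates, which the design text calls biological. Each library was placed in its group by its title, and each of the 36 data columns used was matched to a library by name.

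The authors deposited a table of read counts for 62710 Ensembl genes, in whole numbers and not normalized. STAR 2.7.10, edgeR and the human build hg38 are named per the submitters' processing notes, without their roles. The gene annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes, and genes with near-identical copies, are uncertain. The table holds no entries other than genes. A symbol was found for 62639 of the gene identifiers in the reference name table. The authors also deposited a table of 721551 splicing events with the percent spliced in (PSI) per library, that is, the percent of reads that include the exon, intron or splice site. Beside each percent the authors' table holds a text field with quality scores and the corrected reads for inclusion and exclusion, per the file headers and the layout of the cells. The layout is that of vast-tools; its version and settings are not given in the sources used here. The deposited PSI lay within 0.05 points of the PSI computed from those reads in 100% of the 4562538 values compared. Event coordinates are those of the authors' table on hg38.

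The total count per library ranged from 32487927 to 53985468. With 2 libraries per group, an exact permutation test of 1 group against another cannot go below p = 0.333, so the tests across all genes or events take their spread from all 12 libraries in a fit of 6 group means with 6 residual degrees of freedom. Expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, glmQLFit and glmQLFTest) on the counts as deposited, over 20593 genes, with Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 0.098. Fold changes are fitted log2 values with their standard errors (SE), and levels are the CPM values of edgeR, with TMM-scaled library sizes, given as mean ± SD.

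Splicing was tested on the inclusion and exclusion reads with a quasi-binomial logistic model of the 6 group means, with the dispersion moderated across events (prior degrees of freedom 9.91) and floored at 1, a two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment. An event was tested if it had at least 20 reads in each library and at least 24 reads of its less used form over all libraries, which left 100380 events in 10694 genes. An event was called changed at an adjusted p under 0.05 and a difference of mean PSI of at least 10 points. Each site of an alternative splice site event entered as an event of its own, so 1 change can count once up and once down. Such entries are not independent in the counts and tests of events. Counts of distinct events take the sites of such an event together. Microexons are cassette exons of 27 nt or shorter. The 4 planned comparisons of the target exons come from the same model, and their p-values were also adjusted over those 4 tests. Exact two-sided permutation tests compared the libraries with a guide against all others. Intervals of the PSI of single libraries are 95% Wilson intervals; they cover counting error only, since reads without molecular identifiers are not independent molecules. Exons were placed on the transcripts of GENCODE release 29 (GRCh38).

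Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over 16 lists, again with an estimated correlation, and with fry. The lists were SR proteins; hnRNP and PTB proteins; U1 snRNP and RBM25-related factors; RBFOX, MBNL, CELF and neuronal splicing factors; factors of nonsense-mediated decay (NMD); interferon response; ER stress and integrated stress response; heat shock; p53 targets; mitosis and proliferation; cholesterol synthesis; immediate early genes; mitochondrially encoded mRNAs; replication-dependent histones; neuronal genes; and markers of other cell types (fibroblast, blood, epithelial). BTG2 and ATF3 each stand in 2 of these lists. A further list holds 52 genes with exons known as RBFOX targets. Two-sided Fisher's exact tests compared event types, RBFOX target genes, and genes changed in expression with genes changed in splicing. They treated all genes or events as equally likely to be called. No matching on read depth or on the number of tested events per gene was done. The overlap of the effectors' changes was set against 20 simulations of unchanged groups that share the dCasRx_NT libraries, and, chosen after seeing the data, computed with a different dCasRx_NT library as the control of each effector. The RBM25 binding sequence CGGGCA was counted in called cassette exons and in exons with a PSI difference under 5 points, for the 40257 (82.5%) of 48824 tested cassette exons found in the reference transcripts. The test of a set with sequence for fewer than 80% of its exons is void and its value is not given, because the exons left out may differ from the others. Whether the sequence is more frequent in the void sets therefore stays open, and the sets that are given do not answer for them. The RBFOX sequence GCATG in flanking introns was not analysed here, because no genome sequence was used.

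The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names MAPT, CD46, RBM25, RBFOX1 and RBFOX2. For each comparison of effectors it adds up to 8 genes up and 8 down with the largest fold change among those called, with a mean of at least 1 CPM, a symbol and no overlap between the groups' libraries, and up to 4 members of each list with the smallest adjusted p. For each comparison of guides it adds up to 4 genes up and 4 down. For splicing it names the tested events of MAPT, CD46 and BCL2L1, up to 6 events up and 6 down with the largest PSI difference, and up to 6 called events of the RBFOX target list with the smallest adjusted p. From these, the text gives mainly the genes and events that stayed called when any 1 library of the groups compared was left out. Some genes picked by the rule are not reported here.

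The tests were checked on simulated data made from these libraries. With 100 genes changed 1.5-fold and 100 changed 2-fold between RBM25_MAPT and RBM25_NT among 20030 genes, edgeR found 46 and 92 of them, with 15 false calls. With 100 of 96817 events changed by 15 points and 100 by 30 points, the splicing model found 34 and 79, with 5 false calls. The alternatives tried were DESeq2 1.42.0, other size factors, no filter on low counts, a fit of only the 2 groups compared, the replicate number as a block, other read minimums, a difference of at least 15 points, limma on logit values, PSI from summed reads, and each library left out. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Pseudogenes were matched to coding transcripts with BLAST 2.17.0.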

Results

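Poly(A) RNA-seq libraries were made from HEK293T cells that carried 1 of 3 dCasRx effectors and 1 of 3 guide RNAs, in 6 groups of 2 biological replicates. The dCasRx_NT libraries held 32487927 and 34499904 counts, RBM25_NT 43189146 and 53985468, RBM25_MAPT 46469351 and 39428093, RBM25_CD46 43454892 and 47309345, RBFOX1N_NT 33690196 and 41225760, and RBFOX1N_MAPT 38446952 and 35959403. Replicates differed by more than sampling noise in each group, with a chi-square of 6.49 to 36.3 per gene. Counts at the RBM25 gene, which include the effector's own RBM25 part, took 4.08% to 5.69% of all counts in the 6 libraries with dCasRx-RBM25 and 0.02% to 0.038% in the 6 others. The RBFOX1 gene had 0 to 6 counts in every library, RBFOX1N-dCasRx-C libraries included, so its count does not check that label. In a principal component analysis, the first component (41.5% of the variance) placed the RBFOX1N libraries at 45.3 to 54.3, dCasRx_NT at -9.99 and -3.94, and the RBM25 libraries at -34.7 to -26.8. The second (18.2%) placed dCasRx_NT replicate 2 at 70.1 and replicate 1 at 30.3, with all others between -15.2 and -3.77.

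The MAPT guide was designed to activate exon 10 of MAPT, the gene of the microtubule-associated protein tau, whose exon 10 codes for a microtubule-binding repeat. This 93 nt exon lies on the plus strand of chromosome 17 at 46010310 to 46010402 (hg38), inside the gene at 45894382 to 46028334, and is coding in each of the 9 of 12 annotated coding transcripts that carry it. With dCasRx-RBM25, its PSI rose from 3.00% ± 0.177 (SD, n = 2) under the nontargeting guide to 42.8% ± 4.58 (SD, n = 2) under the MAPT guide. With RBFOX1N-dCasRx-C, it rose from 2.01% ± 0.962 to 14.9% ± 6.22 (SD, n = 2). PSI was 2.68% ± 2.31 in dCasRx_NT and 2.87% ± 0.099 in RBM25_CD46 (SD, n = 2). The 2 RBM25_MAPT libraries gave 39.6% (Wilson interval 33.7 to 45.8) and 46.1% (38.1 to 54.3), and the 2 RBFOX1N_MAPT libraries 10.5% (6.07 to 17.6) and 19.3% (13.6 to 26.7), from 96 to 245 reads per library over all groups.

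The gain of 39.8 points with dCasRx-RBM25 (SE 3.24; 14.3-fold) passed the quasi-binomial test over all 100380 events, with an adjusted p of 0.00027. The gain of 12.9 points with RBFOX1N-dCasRx-C (SE 4.45) passed over the 4 planned tests, with an adjusted p of 0.000292, but not over all events, where the adjusted p was 0.52. No library held dCasRx alone with the MAPT guide. The part of the fused splicing factor in these gains therefore cannot be told apart from that of dCasRx itself. Under the MAPT guide, the exon was included 27.9 points more with dCasRx-RBM25 than with RBFOX1N-dCasRx-C (SE 5.46; adjusted p 0.0017 over all events, quasi-binomial model). The gains themselves differed by 26.9 points, and on the logit scale of the model this interaction had a p of 0.148 (Wald test). That test compares changes of the odds of inclusion, not of points. It also rests on 1.46 and 2.99 inclusion reads in the RBFOX1N_NT libraries, so it does not decide whether the gains differ in points. The 4 libraries with the MAPT guide lay at 10.5% to 46.1% and the 8 others at 1.05% to 4.31% (exact permutation p = 0.00404, the smallest that 495 splits allow). With limma on logit values in place of the quasi-binomial model, the adjusted p over all events was 0.181 for dCasRx-RBM25 and 0.152 for the difference between the effectors under the MAPT guide.

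The CD46 guide was designed to repress exon 13 of CD46, the gene of a membrane protein that regulates complement. This exon of 93 nt lies on the plus strand of chromosome 1 at 207790253 to 207790345 (hg38), inside the gene at 207752057 to 207795513; 3 of 11 annotated coding transcripts carry it, partly as coding sequence, and 8 skip it. With dCasRx-RBM25, PSI fell from 34.9% ± 3.92 (SD, n = 2) under the nontargeting guide to 16.4% ± 1.37 (SD, n = 2) under the CD46 guide. The RBM25_CD46 libraries gave 15.5% (Wilson interval 11.6 to 20.3) and 17.4% (13.6 to 22), from 186 to 412 reads per library over all groups. PSI was 35.3% ± 0.87 in dCasRx_NT, 30.9% ± 4.19 in RBM25_MAPT, 29.8% ± 0.495 in RBFOX1N_NT and 24.3% ± 1.24 in RBFOX1N_MAPT (SD, n = 2). The difference of -18.4 points (SE 2.94) passed over the 4 planned tests with an adjusted p of 9.6e-06 and missed the threshold over all events, with an adjusted p of 0.0688, the rank of its p being 7. Since dCasRx alone was not given the CD46 guide either, the part of RBM25 in this fall cannot be told apart from that of dCasRx. The 10 libraries without this guide lay at 23.4% to 37.6% (exact permutation p = 0.0303, the smallest that 66 splits allow).

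**Figure D1:**
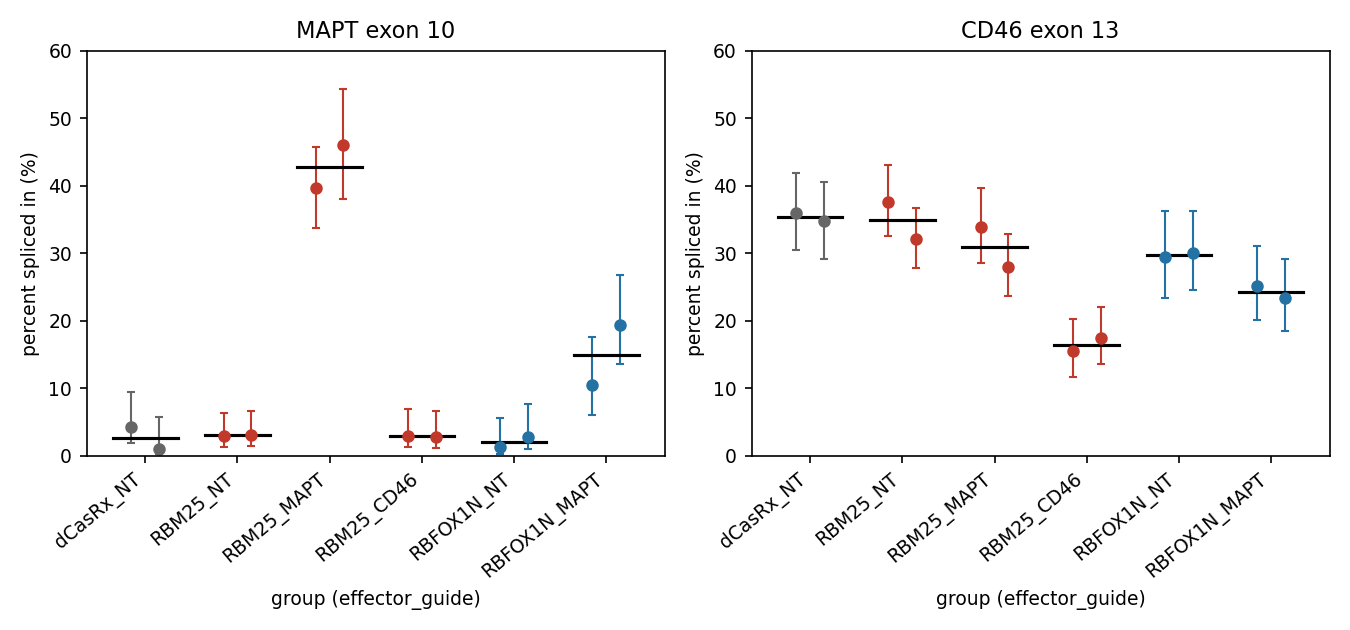
Percent spliced in of MAPT exon 10 and CD46 exon 13 (y axis, %) in the 6 groups (x axis); points are libraries with their 95% Wilson intervals, and horizontal lines are group means. MAPT exon 10 reaches 39.6% and 46.1% in the RBM25_MAPT libraries, and CD46 exon 13 is at 15.5% and 17.4% in the RBM25_CD46 libraries.

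Comparing each guide with the nontargeting guide for the same effector asks what else the guide changed. For splicing, MAPT exon 10 was the 1 event called with dCasRx-RBM25 and the MAPT guide, and it stayed called without any 1 of the 4 libraries. None of the other 7 tested MAPT events, the 14 of CD46 or the 5 of BCL2L1 was called under a guide. The BCL2L1 events were an exon of 157 nt and alternative splice sites 18 and 129 nt apart. None of them was identified as the choice that makes the known short apoptotic form of this gene. An alternative 3' splice site of CD46 at 207785619 to 207785682, in the exon before the target, went from 93.2% to 86.6% under the CD46 guide without passing (unadjusted p 0.0527, quasi-binomial model). The model called 0 events for the CD46 guide, 0 for the MAPT guide with RBFOX1N-dCasRx-C and 0 for the interaction, with 5923, 5949 and 3596 events at an unadjusted p under 0.05; limma on logit values called 0 events for the MAPT guide with dCasRx-RBM25 and 1 for the CD46 guide, an exon of SIDT2 (named after its value was seen). Leaving out RBM25_NT replicate 1 gave 9 events for the MAPT guide and 6 for the CD46 guide, in ZFAND2B, MOV10 and PDS5A for both, and other libraries left out gave at most 4.

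For expression, MAPT itself differed by -0.07 and -0.04 (log2) under its guide with dCasRx-RBM25 and RBFOX1N-dCasRx-C, and CD46 by -0.01 under its guide, each with an SE of 0.11. MAPT stood at 52.2 ± 4.32 CPM in RBM25_NT and 39.0 ± 1.15 CPM in RBFOX1N_NT, and CD46 at 95.8 ± 0.519 and 83.7 ± 4.18 CPM (SD, n = 2). edgeR called 0 of 20593 genes for the MAPT guide with dCasRx-RBM25, 0 for the CD46 guide, 0 for the MAPT guide with RBFOX1N-dCasRx-C and 0 for the interaction, with 1026, 487, 418 and 765 genes at an unadjusted p under 0.05. For the CD46 guide and RBFOX1N-dCasRx-C these were 2.36% and 2.03% of genes, below the share expected without any change. The spread was pooled over groups of unlike replicate noise, from 6.49 per gene in RBM25_CD46 to 36.3 in RBM25_MAPT. A fit of only the 2 groups compared called 8 and 4 genes there, so these 0 calls do not show that nothing changed. DESeq2 called 4, 3, 0 and 0: SAP30, CHASERR and ENSG00000289281 under both guides with dCasRx-RBM25, and TXNDC5 under the MAPT guide (named after their values were seen). Without RBM25_MAPT replicate 1, 555 genes were called for the MAPT guide, 530 of them lower, and without replicate 2 17 genes. The effects of the MAPT guide with the 2 effectors had a correlation of -0.028 across genes and 0.018 across events; genes and events are not independent replicates.

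Some gene lists shifted slightly under the guides, with no single member called. Replication-dependent histones were higher with dCasRx-RBM25 and the MAPT guide (median log2 fold change 0.31; camera adjusted p 0.000478; adjusted p = 0.0645 with an estimated correlation), as were mitosis genes (0.07; 0.0397; adjusted p = 0.786 with an estimated correlation), the latter not without RBM25_NT replicate 1 or RBM25_MAPT replicate 2. Under the CD46 guide, the RBFOX, MBNL and CELF list (median 0.10; adjusted p = 0.334 with an estimated correlation) and the interferon list (0.11; adjusted p = 0.465 with an estimated correlation) were higher, both at a camera adjusted p of 0.035, and neither without RBM25_NT replicate 1, RBM25_NT replicate 2 or RBM25_CD46 replicate 1. Immediate early genes were higher with RBFOX1N-dCasRx-C and the MAPT guide (0.11; 0.00205; adjusted p = 0.857 with an estimated correlation), but not without RBFOX1N_MAPT replicate 1. Other lists passed only with a library left out. For the MAPT guide with dCasRx-RBM25 these were hnRNP and PTB proteins without RBM25_NT replicate 2, immediate early genes without either RBM25_MAPT replicate, and the ER stress and mitochondrial lists without RBM25_MAPT replicate 2. For the CD46 guide they were hnRNP and PTB proteins without RBM25_NT replicate 1, and p53 targets without it or RBM25_CD46 replicate 2. For RBFOX1N-dCasRx-C it was the mitochondrial list, without RBFOX1N_NT replicate 2 or either RBFOX1N_MAPT replicate.

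The comparison of dCasRx-RBM25 with dCasRx under the nontargeting guide asks what adding RBM25 changes without a target. Many genes of the p53 target list fell. TP53I3, a quinone oxidoreductase named for its induction by p53, fell by 1.94 on the log2 scale (SE 0.11). SPATA18, PLK3 and the antiproliferative gene BTG2 fell by 1.15, 0.99 and 0.93. The activity of p53 itself was not measured. In all, 15 of 28 tested p53 targets fell and 0 rose, or 20 and 0 adjusted over the list alone, by edgeR; the list median was -0.50 and the camera adjusted p 8e-13, with adjusted p = 0.0675 with an estimated correlation. INPP5D, a phosphatase of inositol lipids, fell the most of the named genes, by 3.49 (SE 0.18; edgeR adjusted p 4.71e-07), to 3.19 ± 0.944 from 35.5 ± 1.96 CPM (SD, n = 2). The fatty acid hydroxylase genes CYP4F2 and CYP4F3, a pair of similar copies, fell by 3.07 and 2.92, the potassium channel gene KCNN4 by 2.83, FRMPD2 by 2.78, the mucin gene MUC19 by 2.49 and the cell adhesion gene NECTIN4 by 2.43.

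RBM25 counts rose by 7.31 (SE 0.24) to 44090 ± 2500 from 278.2 ± 105 CPM (SD, n = 2; edgeR adjusted p 2.71e-09). The extracellular matrix gene TNN rose by 2.74 (SE 0.18) and FERMT3, which codes for an integrin activator of blood cells, by 2.55 (SE 0.17), to 26.98 ± 5.43 from 4.60 ± 0.329 CPM. ACTG1P3, KRT8P36, DFFBP1, TNRC18P1 and KRT8P39 rose by 2.39 to 3.17; these are pseudogenes, whose counts can hold reads of their parent genes. Other called genes were DDIT3, a transcription factor of the stress response (-0.97), the interferon-induced IFI35 (-1.93), and the cholesterol synthesis genes HSD17B7 (-0.58) and PMVK (-0.50). MAPT (0.34), CD46 (0.10) and RBFOX2 (0.18) were not called.

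By list, 5 of 30 immediate early genes rose and 2 fell (10 and 3 adjusted over the list alone), with a median of 0.25 and a camera adjusted p of 0.0407, and adjusted p = 0.789 with an estimated correlation; this call was lost without dCasRx_NT replicate 2 (0.18) or RBM25_NT replicate 1 (0.055). The 14 other lists did not pass, with adjusted p of 0.0544 for U1 snRNP and RBM25-related factors, 0.106 for neuronal genes, 0.122 for interferon response, 0.225 for ER stress and 0.228 for SR proteins. It was 0.344 for heat shock, 0.455 for NMD factors, 0.465 for hnRNP and PTB proteins and for mitosis, and 0.651 for cholesterol synthesis, histones and the RBFOX, MBNL and CELF list. Mitochondrial mRNAs were at 0.684 and markers of other cell types at 0.79, with medians of 0.08 and 0.05. The U1 snRNP list passed without dCasRx_NT replicate 1 and without RBM25_NT replicate 2.

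Over all 20593 genes, edgeR called 800 higher and 770 lower in RBM25_NT than in dCasRx_NT, 190 and 324 of them at least 2-fold. The total of 1570 was 599 without dCasRx_NT replicate 2 and 368 without RBM25_NT replicate 1, 636 in a fit of only these 2 groups and 2647 with no filter on low counts. The balance of genes higher and lower varied: 719 and 842 with RLE size factors, 815 and 1233 without dCasRx_NT replicate 1, 249 and 350 without its replicate 2, 175 and 193 without RBM25_NT replicate 1, and 653 and 431 without RBM25_NT replicate 2.

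With dCasRx-RBM25, cassette exons were called less included more often than more included. PSI of an exon of the kinase gene WNK4 (chromosome 17, 42787778 to 42787899) fell from 97.8% to 56.8%, and that of a GOLIM4 exon (chromosome 3, 168040786 to 168040869) from 83.4% to 62.0%. An exon of ARHGEF11 (chromosome 1, 156943935 to 156944102) went from 100% to 83.8%. In SYNCRIP, which codes for an hnRNP, use of an alternative 5' splice site (exon at 85622482 to 85622675 on chromosome 6) fell by 47.4 points to 26.3%, and in the chaperone gene HSP90AB1 an alternative 3' splice site (exon at 44253045 to 44253372 on chromosome 6) rose by 45.2 points to 88.0%; HSP90AB1 has near-identical copies in the genome. These events were kept without any 1 library. The replicates of WNK4 and SYNCRIP in RBM25_NT had SDs of 2.91 and 0.226 points (n = 2). These events had as few as 34 and 35 reads in a library over all groups. With so few reads, a small SD of 2 libraries does not show a low spread.

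The quasi-binomial model called 735 events (694 distinct) in 560 genes, 290 up and 445 down. Of cassette exons over 27 nt, 169 rose and 370 fell, and they made up 73.3% of called against 48.2% of tested events (Fisher's exact odds ratio 2.98, adjusted p 3.2e-43). Of retained introns, 69 rose and 26 fell (odds ratio 0.384). The sequence CGGGCA stood in 4 (2.88%) of the 139 more included exons with sequence, against 2.48% of unchanged exons (Fisher's exact p = 0.78), and the set of less included exons was void, with sequence for 78.3%. RBFOX target genes had a called exon in 4 of 50 (Fisher's exact adjusted p 0.452). Genes changed in both expression and splicing numbered 57 against 38.3 for independent calls (Fisher's exact p = 0.0024), with no matching on read depth or number of events. The count of 735 was 427, 237, 461 and 454 without dCasRx_NT replicate 1, dCasRx_NT replicate 2, RBM25_NT replicate 1 and RBM25_NT replicate 2, and the balance of events up and down was 119 and 342 without RBM25_NT replicate 1 and 216 and 238 without its replicate 2. The count was 62 with limma on logit values.

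The comparison of RBFOX1N-dCasRx-C with dCasRx asks the same of the RBFOX1 parts. Most immediate early genes and some stress genes rose. GDF15, which codes for a stress-induced cytokine, rose by 2.02 on the log2 scale (SE 0.21), to 232.5 ± 24 from 57.3 ± 0.14 CPM (SD, n = 2; edgeR adjusted p 6.76e-05). The proapoptotic BBC3, the cell cycle inhibitor CDKN1A and BTG2 rose by 1.65, 1.16 and 0.97. Of the immediate early genes, 21 of 30 rose and 0 fell (26 and 0 adjusted over the list alone), with CCN1 at 1.08, KLF6 at 0.87 and KLF10 at 0.70; the median was 0.69 and the camera adjusted p 8e-14, with adjusted p = 0.413 with an estimated correlation.

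Of 28 tested heat shock genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 0.000306, and adjusted p = 0.602 with an estimated correlation. The small heat shock gene HSPB8 rose by 1.40, the cochaperone gene DNAJB1 by 1.04 and HSPA1B, which has a near-identical copy, by 0.96. HSPA6, a stress-inducible member of the same family, fell by 2.15 (SE 0.15), to 5.23 ± 1.34 from 23.1 ± 0.283 CPM (SD, n = 2). Of the ER stress and integrated stress response list, 7 of 36 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p 0.0253; adjusted p = 0.695 with an estimated correlation), with PPP1R15A at 0.84 and SESN2 at 0.76. Of the mitosis list, 8 of 37 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p 0.0035; adjusted p = 0.695 with an estimated correlation). The calls of these last lists were lost without dCasRx_NT replicate 2 or RBFOX1N_NT replicate 1.

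Of p53 targets, 8 rose and 1 fell (10 and 4 adjusted over the list alone), and the list did not pass (median 0.08; camera adjusted p 0.146). The remaining 11 lists had camera adjusted p of 0.171 to 0.968. Among their members, the NMD factor gene SMG9 rose by 0.66, the interferon-induced DHX58 by 1.36 and the keratin gene KRT8 by 1.18. Of 31 tested interferon genes, 3 rose and 2 fell. SR, hnRNP and U1 factors had medians of -0.03, -0.01 and -0.01. The largest increases were those of S100A2, which codes for a calcium-binding protein (5.10, SE 0.22; edgeR adjusted p 3.8e-08), the readthrough gene TPTEP2-CSNK1E (5.07), the lipocalin gene LCN8 (4.92), TGFBR3L (4.18), the pseudogene CHMP4BP1 (4.01), LAPTM5 (3.89), SPACA6-AS1 (3.84) and LINC00482 (3.37). Besides HSPA6, the genes that fell the most, RPS28P4, RN7SL1, PCBP2P2, RN7SL3, TUBAP2, RNU6-1 and RPL21P28, were pseudogenes or small structural RNAs, and none stayed called without dCasRx_NT replicate 2; RN7SL1 stood at 83.3 ± 91.5 CPM in dCasRx_NT (SD, n = 2). MAPT (-0.08), CD46 (-0.10), RBFOX2 (0.02) and RBM25 (-0.42) were not called.

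Over all genes, edgeR called 1548 higher and 669 lower in RBFOX1N_NT than in dCasRx_NT, 656 and 257 of them at least 2-fold. The total of 2217 was 849 without dCasRx_NT replicate 2, 975 without RBFOX1N_NT replicate 1 and 624 without RBFOX1N_NT replicate 2, with 675 higher and 174 lower, 876 and 99, and 530 and 94. Without dCasRx_NT replicate 1, 1615 were higher and 1357 lower.

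With the RBFOX1 parts, called events included splice sites, cassette exons and introns. In SUMO2, which codes for a ubiquitin-like protein, an alternative 5' splice site that lengthens the exon at 75182115 to 75182563 on chromosome 17 rose from 2.59% to 61.1% ± 1.92 (SD, n = 2; quasi-binomial adjusted p 4.63e-07). Exons of the actin regulator CTTN (chromosome 11, 70421470 to 70421580), GOLIM4 and TSC2 (chromosome 16, 2062972 to 2063053), all in the RBFOX target list, were less included, by -20.1, -30.6 and -14.8 points, and an intron of ENAH, also in the list, rose by 14.3 points. Exons of MYO9B (chromosome 19, 17210333 to 17210380), ENO3 (chromosome 17, 4953051 to 4953109) and PPIA (chromosome 7, 44798748 to 44798904) were less included, by -52.9, -50.5 and -50.2 points, and an intron of CPT1C was less retained, by -56.0 points. Exons of ACSF3 (chromosome 16, 89117221 to 89117938) and C17orf53 (chromosome 17, 44142678 to 44142772) rose by 51.5 and 46.9 points. PPIA has many near-identical copies in the genome.

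The model called 1147 events (1089 distinct) in 841 genes, 609 up and 538 down. Retained introns rose in 225 and fell in 56 cases, fewer than their share of tested events (Fisher's exact odds ratio 0.842). Microexons were called in 18 cases, 13 up and 5 down, which is 3.96% of those tested (Fisher's exact odds ratio 3.61, adjusted p 1.15e-05). Cassette exons over 27 nt rose in 309 and fell in 411 cases (odds ratio 1.83). RBFOX target genes had a called exon in 7 of 50 (14%), against 6.3% of other genes (Fisher's exact adjusted p 0.0742). CGGGCA stood in 3 (1.15%) of 260 more included exons with sequence (Fisher's exact adjusted p 0.452), and the set of less included exons was void, with sequence for 76.4%. Genes changed in both expression and splicing numbered 163 against 81.2 for independent calls (Fisher's exact adjusted p 4.56e-19). Without matching on read depth or number of events, part of this excess may come from genes that are easier to call. The count of 1147 was 748, 483 and 472 without dCasRx_NT replicate 1, dCasRx_NT replicate 2 and RBFOX1N_NT replicate 2, and 296 with limma on logit values.

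**Figure D2:**
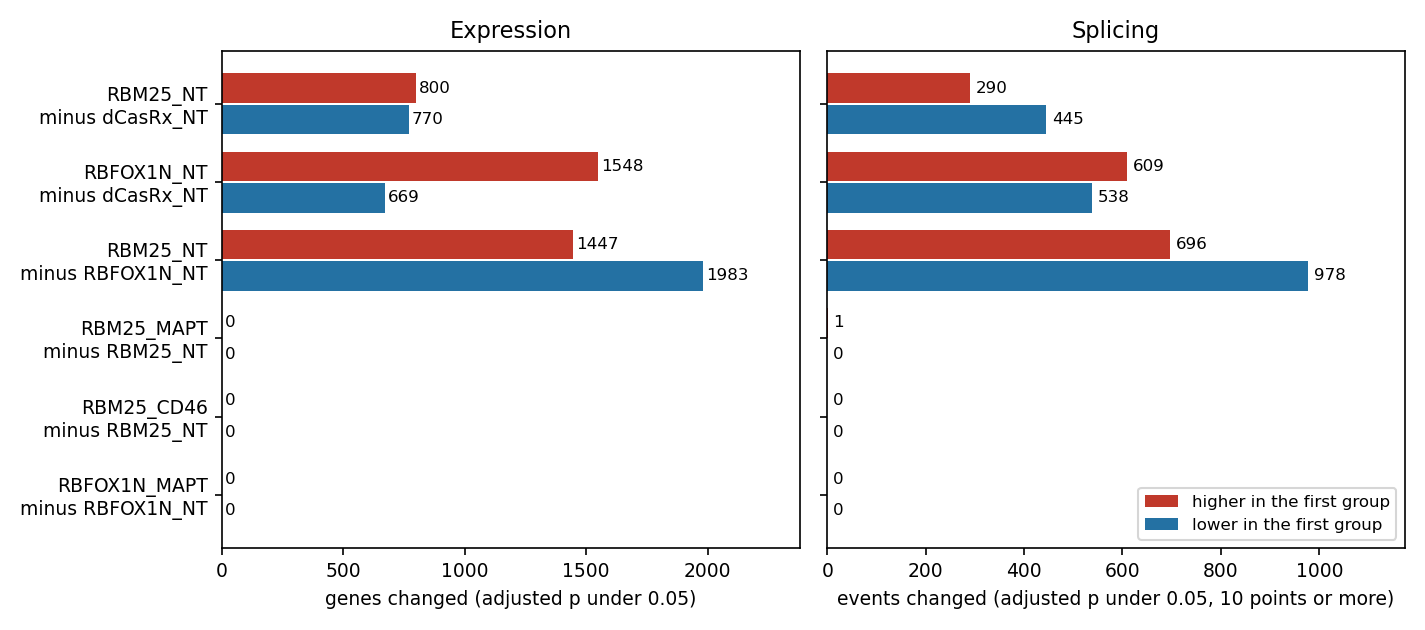
Numbers of genes and of splicing events called higher or lower (x axis) in each comparison (y axis). The 3 comparisons of effectors give 1570, 2217 and 3430 genes, and the comparisons of guides give 0 genes and at most 1 event.

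The direct comparison of dCasRx-RBM25 with RBFOX1N-dCasRx-C asks where the effectors differ. It does not compare the dCasRx_NT libraries, though they enter the fit that gives the spread. GDF15 was lower with dCasRx-RBM25 by a log2 fold change of -3.57 (SE 0.22), at 19.7 ± 4.83 against 232.5 ± 24 CPM (SD, n = 2; edgeR adjusted p 7.77e-07), as were TP53I3 (-2.58), BTG2 (-1.90) and CDKN1A (-1.88). Of 28 p53 targets, 18 were lower and 0 higher (20 and 1 adjusted over the list alone), with a median of -0.61 and a camera adjusted p of 3.22e-11, and adjusted p = 0.0933 with an estimated correlation. Of 30 immediate early genes, 13 were lower and 0 higher (17 and 0 adjusted over the list alone; median -0.43; camera adjusted p 1.81e-06; adjusted p = 0.531 with an estimated correlation), among them FOSL1 (-1.57), ATF3 (-0.77) and KLF10 (-0.62). Of 28 heat shock genes, 13 were lower and 1 higher (15 and 1 adjusted over the list alone; median -0.32; camera adjusted p 4.21e-05; adjusted p = 0.468 with an estimated correlation), with HSPB8 at -1.81, DNAJB1 at -1.05 and HSPA1B at -0.82, and HSPA6 higher at 1.47.

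S100A2 was lower by -7.28 (SE 0.26; edgeR adjusted p 3.09e-09), followed by LINC00482, LCN8, SPACA6-AS1, GAS6-AS1, LAPTM5, TPTEP2-CSNK1E and the smooth muscle gene CNN1, at -5.46 to -4.13. Higher with dCasRx-RBM25 were RBM25 (7.73), the pseudogenes ACTG1P3 (3.82) and DFFBP1 (2.29), TNN (2.63), the steroidogenic transcription factor gene NR5A1 (2.16), STC1 (2.12), C1QTNF12 (2.10) and TMEM119 (2.00). The stress genes SESN2 (-1.20) and DDIT3 (-1.30), the cyclin gene CCNE1 (-0.66), IFIT2 (-2.45) and KRT8 (-1.23) were lower, and VLDLR (0.68), INSIG1 (0.49), RBM8A (0.55) and the histone genes H1-2 (1.02) and H2BC21 (0.61) higher. MAPT was higher by 0.42 (edgeR adjusted p 0.0203), a call lost without RBM25_NT replicate 1, RBFOX1N_NT replicate 1 or RBFOX1N_NT replicate 2, and CD46 (0.19) was not called. The 13 other lists did not pass, at camera adjusted p of 0.0604 to 0.83, though the U1 snRNP and mitosis lists did without RBM25_NT replicate 2 and without RBFOX1N_NT replicate 2. edgeR called 1447 genes higher and 1983 lower; the total of 3430 was 1414 without RBM25_NT replicate 1, 1482 without RBFOX1N_NT replicate 1 and 1280 without RBFOX1N_NT replicate 2, with more genes lower than higher each time.

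**Figure D3:**
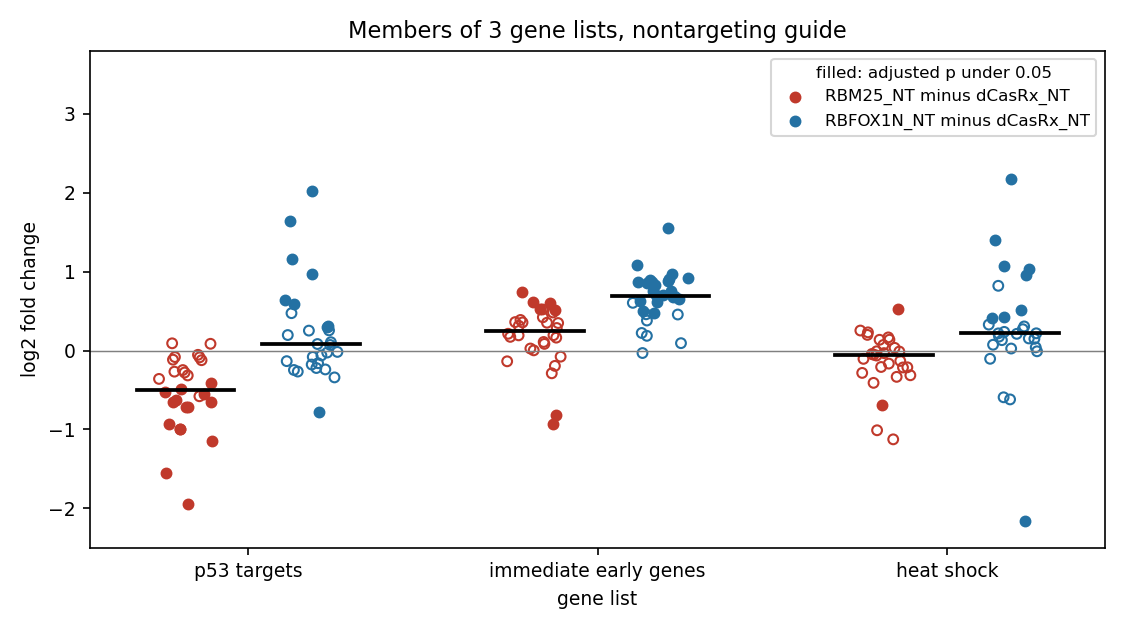
Log2 fold change (y axis) of each tested member of the p53, immediate early and heat shock lists (x axis), for RBM25_NT and RBFOX1N_NT against dCasRx_NT; filled points passed an edgeR adjusted p under 0.05 and black lines are list medians. The p53 median is -0.50 with dCasRx-RBM25 and 0.08 with RBFOX1N-dCasRx-C, and the immediate early median 0.25 and 0.69.

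Splicing also differed between the effectors. An exon of the cochaperone gene PTGES3 (chromosome 12, 56686869 to 56686917) was included in 72.7% ± 5.94 of reads with dCasRx-RBM25 and 13.8% with RBFOX1N-dCasRx-C (SD, n = 2; quasi-binomial adjusted p 9.07e-08). The long form of the SUMO2 exon was lower by -58.8 points, and exons of PPIA, MYO9B and CSF1 (chromosome 1, 109923249 to 109923711) were included 57.0, 56.7 and 49.9 points more. Introns of the glycolytic gene PKM (chromosome 15, 72219111 to 72230899), C17orf53 and ZNF691 were lower by -47.4, -46.0 and -44.8 points. These introns had as few as 22, 44 and 30 reads in a library, near the minimum of 20. Their PSI therefore need not describe most transcripts of the gene. In MAPT, a 753 nt exon at 45983178 to 45983930, upstream of exon 10, was at 11.8% with dCasRx-RBM25 and 0.355% with RBFOX1N-dCasRx-C (adjusted p 0.00282). BCL2L1 had no called event; the PSI of its exon at 31666991 to 31667147 on chromosome 20 was 2.56% and 11.5%, at an adjusted p of 0.0239 but under 10 points apart.

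The model called 1674 events (1618 distinct) in 1186 genes, 696 up and 978 down. Cassette exons over 27 nt rose in 422 and fell in 666 cases (Fisher's exact odds ratio 2.02), and introns in 203 and 235. RBFOX target genes had a called exon in 15 of 50 (30%), against 9.1% of other genes (Fisher's exact adjusted p 0.000161), among them CTTN (16.5 points), FMNL2 (15.5) and CAMK2G (-21.5). The list and the other genes were not matched on read depth or on the number of tested exons. Both sets of exons were void for CGGGCA, with sequence for 73.8% and 77.3%. Genes changed in both expression and splicing numbered 256 against 182.0 for independent calls (Fisher's exact adjusted p 1.78e-09), again with no matching. The count of 1674 was 1107, 1047 and 870 without RBM25_NT replicate 1, RBFOX1N_NT replicate 1 and RBFOX1N_NT replicate 2, and 271 with limma on logit values. Without RBM25_NT replicate 2 the balance turned to 651 events up and 603 down.

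The changes of both effectors against dCasRx_NT share their control libraries. Both raised 211 genes, against 60.1 for independent lists, and both lowered 151 against 25. In opposite directions, 52 genes were called, against 83.9. Lists with shared controls are not independent, so these counts alone do not show a shared effect. The log2 fold changes had a correlation of 0.44 across the 20593 genes (rho 0.389), and 20 simulations of unchanged groups with the same controls gave a mean of 0.521 (SD 0.009). Their covariance was 0.185 against 0.046 simulated, a difference of 0.139. Over the 11443 genes with a mean of at least 5 CPM the correlation was 0.294 and the covariance 0.024 against 0.01. The simulations used a spread pooled over all 6 groups, while the dCasRx_NT replicates had the lowest correlation of any group (0.9925 on log2 CPM). The simulated covariance can therefore be too low, and the difference too large as a measure of shared effects. Without dCasRx_NT replicate 1 the correlation was 0.686. With a different dCasRx_NT library as the control of each effector, it was 0.089 with replicate 1 for dCasRx-RBM25 and 0.167 with replicate 2 for dCasRx-RBM25 (covariance 0.051 and 0.093), so much of the correlation rests on the shared controls.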

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

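The tests of a shift of the control libraries, of GC content and length, and of the RBM25 part were chosen after the p53 pattern had been seen, the first and last of them also after related values of the list were known. The 3 gene lists below stand out because the difference between the effectors was tested directly, in RBM25_NT against RBFOX1N_NT.

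The p53 list was lower with dCasRx-RBM25 than with RBFOX1N-dCasRx-C, with a median log2 fold change of -0.61, and it had also fallen against dCasRx_NT (-0.50). The difference between the effectors cannot come from a shift of the dCasRx_NT libraries, which it does not compare. It was also present in RBM25_MAPT against RBFOX1N_MAPT: the median there was -0.50, with 18 of 28 members lower and 1 higher. That value cannot decide whether a shift of the dCasRx_NT libraries made the list fall against them. Against dCasRx_NT, RBFOX1N-dCasRx-C raised 8 members and lowered 1, which could also give a lower list between the effectors. A bias of GC content or transcript length is argued against by 10000 random lists matched on both and on expression, 95% of whose medians lay between -0.03 and 0.13, against -0.50 for the p53 list. Whether the RBM25 part of the effector lowers p53 targets stays open. The medians of RBM25_MAPT and RBM25_CD46 against dCasRx_NT, -0.45 and -0.39, decide nothing, because they share the dCasRx_NT controls and the guides moved the list by medians of only -0.05 and 0.05. With an estimated correlation the list passed neither against dCasRx_NT (adjusted p = 0.0675) nor between the effectors (adjusted p = 0.0933).

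Immediate early genes differed between the effectors by a median of -0.43, with 13 of 30 lower in RBM25_NT and 0 higher, and adjusted p = 0.531 with an estimated correlation. Heat shock genes differed by a median of -0.32, with 13 of 28 lower and 1 higher, and adjusted p = 0.468 with an estimated correlation.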

How the results depend on the processing

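Chosen after the data were seen were the gene list and overlap tests without single libraries, the overlap with separate controls and the restriction to events that the splicing tool scored above its very low class. Over counts of calls, list tests and target exons, 73 of 103 alternatives stayed within the limits set and 30 moved; with single libraries left out, 61 of 110 stayed and 49 moved. For named genes and events, 1031 of 1123 alternatives kept the call and 92 lost it, and 628 of 884 with a library left out kept it and 256 lost it; 0 reversed in sign. A group left with a single library is assumed to vary like the others. The cause of the changes below was not tested, except where fewer genes, events or libraries entered by construction.

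With no filter on low counts, edgeR called 2647 genes for RBM25_NT against dCasRx_NT, 67 for the MAPT guide with dCasRx-RBM25, 13 for the CD46 guide, 1 (RN7SL1) for the MAPT guide with RBFOX1N-dCasRx-C and 18 for the interaction. For RBM25_NT against RBFOX1N_NT it called 1977 higher and 1875 lower, which turned the balance of that comparison. In a fit of only the 2 groups compared, it called 636 for RBM25_NT against dCasRx_NT, 8 for the CD46 guide and 4 (ATP6V1FNB, MZT1, RN7SL1, RPS21) for the MAPT guide with RBFOX1N-dCasRx-C. DESeq2 called 4 and 3 genes for the MAPT and CD46 guides with dCasRx-RBM25. Requiring 15 points left 360, 651 and 901 events for RBM25_NT, RBFOX1N_NT and their direct comparison; limma on logit values gave 62, 296 and 271, and 0 and 1 for the MAPT and CD46 guides with dCasRx-RBM25. With an estimated correlation, camera called 0 lists in all 6 comparisons. The overlap correlation was 0.294 for genes of at least 5 CPM, and 0.089 and 0.167 with separate controls.

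Leaving out each library gave 368 to 2048 genes for RBM25_NT against dCasRx_NT, 624 to 2972 for RBFOX1N_NT against dCasRx_NT, 1280 to 2417 for the direct comparison, 0 to 555 for the MAPT guide with dCasRx-RBM25, 0 to 114 for the interaction, and 0 to 0 for the CD46 guide and for the MAPT guide with RBFOX1N-dCasRx-C. For events in that order it gave 237 to 461, 472 to 781, 870 to 1254, 3 to 9, 0 to 0 for the interaction, 0 to 6 for the CD46 guide and 0 to 3 for RBFOX1N-dCasRx-C. Lists called numbered 1 to 3, 2 to 4, 3 to 5, 1 to 4, 0 to 3 and 1 to 2. The MAPT exon 10 difference was 36.6 to 43.1 points with dCasRx-RBM25, 8.5 to 17.3 with RBFOX1N-dCasRx-C and 23.5 to 32.3 between them; that of CD46 exon 13 was -21.2 to -15.7, and the overlap correlation 0.384 to 0.686.

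The replicate numbers share no named batch, and deviations of same-numbered libraries had correlations of -0.098 to 0.166 between groups. With the replicate number as a block, 383 and 674 events were called for RBM25_NT and RBFOX1N_NT against dCasRx_NT and 1 list for the MAPT guide with dCasRx-RBM25. That list was the replication-dependent histones, and the call of the mitosis list was lost. The blocked gene counts were 1966, 2614 and 3897 for the effectors and 0 for each guide, and the blocked MAPT exon 10 gain of 39.8 points had an adjusted p of 0.0218 over all events.

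MAPT exon 10 rests on 96 to 245 reads per library. The tests with 100 nt and 300 nt of intron for GCATG were not run.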

Other observations

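All tests on dCasRx_NT replicate 2 and RBM25_MAPT replicate 2 in this part were chosen after those patterns had been seen; those of parent gene reads and of depth were also written after related values were known. The comparison under the MAPT guide in the next paragraph was likewise added after the data were seen.

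The difference between the effectors was also present under the MAPT guide, in libraries other than those of the nontargeting comparison. Both comparisons came from the same fit of all 12 libraries, with a shared gene filter and spread. Their calls are therefore not fully independent. edgeR called 4660 genes between RBM25_MAPT and RBFOX1N_MAPT, and of the 3430 called under the nontargeting guide, 2462 were called in the same direction and 99.1% had the same sign; the fold changes had a correlation of 0.764 across 20593 genes. SAP30 and CHASERR, which DESeq2 called under both guides with dCasRx-RBM25, were at 0.79 and 0.80 with both guides pooled against RBM25_NT, at an edgeR adjusted p of 0.535; that test called 0 genes, with 661 at an unadjusted p under 0.05, and was not run in another tool. RBM25 took 0.038% of counts in dCasRx_NT replicate 2, against 0.022% in replicate 1 and 0.02% to 0.023% in the RBFOX1N libraries.

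Processed pseudogenes were higher in dCasRx_NT replicate 2 than in the other libraries: their median deviation exceeded that of coding genes by 1.15 on the log2 scale, against -0.20 to 0.35 elsewhere, over 1090 pseudogenes and 14611 coding genes. Among genes lower with RBFOX1N-dCasRx-C than with dCasRx, 94 (14.1%) of 669 were processed pseudogenes, against 5.3% of tested genes; among those lower with dCasRx-RBM25 than with dCasRx they were 10 (1.3%) of 770. Length or GC bias is argued against as the whole cause, since the difference to matched coding genes was 0.85 (SD over pseudogenes 1.14). Genomic DNA stays open: intron PSI changed by a median of 0.02 points between the replicates over 27885 introns, but other groups ran from -0.26 to 0.64, too wide a spread to decide. Reads of parent genes counted at pseudogenes may contribute: pseudogenes whose best coding match had at least 500 CPM deviated by 1.17 more than those with a match under 50 CPM (414 and 211 of 1016 matched, 93.2% of the set). No biological explanation was tested.

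Without RBM25_MAPT replicate 1, 530 genes were lower under the MAPT guide. The guide is argued against as their cause: in the fit without replicate 2 the same genes had a median of -0.02 (SD 0.12), against -0.59 without replicate 1. Depth is argued against by the total count of replicate 2, 0.85 of that of replicate 1. A GC bias of replicate 2 is consistent with the difference between the replicates, -0.77 for the 1462 coding genes of highest against the 1462 of lowest GC content, and with the median GC content of the lower genes, 64.4% against 50.2% for all tested genes with a value (95.4%).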
